A study of Mus musculus with 34 samples.

How the data were processed

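RNA of B cells was sequenced from visceral adipose tissue (VAT) and spleen of wild-type (WT) mice and of mice without Nlrp3 (knockout, KO). Per the labels, the sorted cells were live CD45-positive, B220-positive and CD19-positive, and negative for CD3, CD11b, CD93, CD21 and CD23. Libraries were made by oligo(dT) priming and amplification of full-length cDNA from very small amounts of RNA. The labels place each library in 1 of 3 cohorts. They give 2 RNA extraction batches, and an age only for cohort 3, where libraries are young or old. Replicates 1, 2 and 3 of each group without an age belong to cohort 1, and replicates 4 and 5 to cohort 2.

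The authors quantified reads with kallisto against mm10 and normalized them with DESeq2, per the labels, which give no versions. Each of the 4 deposited tables holds 1 normalized signal value per gene and library, as the authors scaled it within that table. Among the low values above 0 of a library, 5.71% to 79.1% lay within 0.1 of a whole multiple of 1 step fitted to that library. The values were therefore not treated as read counts. The depth of each library is unknown, no counting interval was computed, and no model for read counts was used. The sum of the normalized values per library was 26555000 to 30280100 in the VAT table, 28614500 to 35726500 in the spleen table, 25247300 to 28721500 in the table of both tissues and 9976500 to 17939400 in the table of old and young mice. The first pair of tables holds coding and noncoding genes, and the other pair protein-coding genes. At least 99.7% of the gene identifiers in every table matched the GENCODE M21 annotation of GRCm38, from which coordinates were taken.

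The VAT table held WT replicates 1, 3 and 5 and KO replicates 1 to 4. The spleen table held WT replicates 1, 3, 4 and 5 and KO replicates 1 to 4. The table of both tissues held WT libraries: VAT replicates 1 to 5 and spleen replicates 1, 3, 4 and 5. The table of old and young mice held VAT libraries of cohort 3: 3 young WT, 1 old WT and 3 old KO. Values were compared only within a table, except in the closing section. There 1 test sets levels relative to B cell reference genes in VAT of cohort 3 against those in spleen of another table. Values of Hspa1a and Hspa1b from both tables are given beside it. The tissue comparison in KO, a fit of tissue and genotype together, and every comparison of cohort 3 spleen need libraries that stand in no common table, and were not analysed here. No library pair within a table held identical values at any gene above 0, and the highest Spearman correlation between libraries was 0.961.

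Values were log2 transformed after adding 1, and fold changes are differences on this scale. Each gene with a value of at least 10 in as many libraries as the smaller group was tested, 2-sided, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the variance on the mean). P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Cohort was a term in the comparisons of cohorts 1 and 2. In cohort 3 all 3 groups shared 1 spread, and the lone old WT library was assumed to vary like the others. The labels do not say that replicates came from separate mice, so p-values measure the spread between these libraries. For a difference of the genotype effect between tissues, the within-table fold changes were subtracted and divided by their joint standard error. Single values were compared by exact permutation of the genotype labels. The genotype effects on list means were compared between tissues by permuting genotype within tissue, and within tissue and cohort. All these tests of a genotype effect that differs between tissues were chosen after the values were seen.

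The 38 gene lists, the tests within a table, the alternatives not said to be added later, and the rule for named genes were fixed before the data were examined. Each list was tested with camera of limma at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry, adjusted over the lists of a comparison. Camera compares a list with all other genes. Fry tests whether the members of a list move, on balance, in 1 direction. For each list the members past the threshold over all genes are given, and the number when adjusted over the list alone. The named genes were Nlrp3 in genotype comparisons, the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 value of at least 5 in the higher group, and up to 4 members of each list with a member past it. Where no gene passed, the 3 with the lowest p are named. Symbols of unnamed gene models and of immunoglobulin and T cell receptor segments were left out. Other genes are said to have been chosen after their values were seen.

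The tests were checked on simulated data with the same libraries' spread. A random set of genes with a mean log2 value above 5 carried a known change, and the noise was drawn independently for each gene. The shares called therefore do not hold for low genes such as Nlrp3, or for genes that vary together. At a log2 change of 2, 62.7% of the changed genes were called in the VAT genotype comparison, 65.7% in the spleen genotype comparison and 79.1% in the tissue comparison. In cohort 3 at a log2 change of 4, 4.55% were called for age in WT, 19.7% for genotype and 50% for old libraries of both genotypes against young.

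Alternatives were other pseudocounts, other filters, rescaling of every library to the same total, quantile normalization, sample quality weights, leaving out each library in turn, no cohort term, cohort 1 alone and the replicate number as a block. Libraries of the same replicate number deviated together from their group means in the spleen genotype comparison, with correlations of 0.155, 0.131 and 0.185. With the cohort means removed these became -0.13, -0.10 and -0.54. Every such correlation was also negative in the other comparisons of cohorts 1 and 2, since removing means from few libraries pulls it down. This cannot tell a pairing by number from the cohort, which the model holds as a term. The replicate block called 0 genes in the spleen genotype comparison. The comparison of old libraries of both genotypes against young, and a sex term in it, were added after the values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.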

Results

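The series profiles B cells sorted from visceral adipose tissue (VAT) and spleen of wild-type (WT) mice and of mice without Nlrp3 (KO), the sensor of an inflammasome that activates caspase-1 and IL-1 family cytokines. The design names tissue, genotype and age as the factors. In cohorts 1 and 2 the tables held 3 WT and 4 KO libraries of VAT for the genotype comparison, 4 WT and 4 KO libraries of spleen, and 5 WT libraries of VAT beside 4 of spleen for the tissue comparison. In cohort 3 they held VAT libraries of 3 young WT, 1 old WT and 3 old KO mice. Values are normalized signals per gene, with log2 fold changes computed on log2(value + 1); the number of reads behind a value is unknown.

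Nlrp3 (ENSMUSG00000032691.14; chromosome 11, 59541568 to 59566956, plus strand) had low values in every library. In VAT of cohorts 1 and 2 it stood at 85.4, 10.8 and 65.1 in the WT libraries and at 10.1, 0, 15.7 and 4.27 in the KO libraries, a log2 fold change of -2.83 (SE 1.20, adjusted p = 0.672). In the spleen it stood at 0, 6.34, 0 and 18.3 in WT and at 14.4, 19.4, 4.69 and 0 in KO, so the level there does not tell the genotypes apart. In cohort 3 it stood at 57.8, 46.8 and 0 in young WT, at 15.7 in the old WT library and at 2.33, 0.436 and 1.10 in old KO. Within WT, Nlrp3 was higher in VAT than in spleen by 3.79 (SE 1.04, adjusted p = 0.0229).

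The first comparison asks how adipose B cells differ without Nlrp3, with 4 KO against 3 WT libraries. No gene passed the test. Macrophage and monocyte markers had lower values in KO for all 15 members tested, with a median log2 fold change of -1.09. Lyz2, a lysozyme, averaged 4437 ± 2221 (SD, n = 4) in KO and 10842 ± 7799.7 (SD, n = 3) in WT, and C1qa, a complement component, 892 and 2188. These mark cells other than those sorted for, and which cells gave the transcripts was not tested. The stromal marker Dcn was uneven in WT, at 8852, 5430 and 36587 in replicates 1, 3 and 5, and 3535 to 17320 in KO. Cytosolic ribosomal protein genes had negative fold changes for all 34 members (median -0.32), and cell cycle genes for 21 of 23 (median -0.51), with Birc5 at -1.08 (SE 0.29). Germinal center genes had negative fold changes for 12 of 14 members (median -0.84), among them Nuggc at -2.45 (SE 0.48) and Aicda, the deaminase of antibody diversification, at -1.65 (SE 0.76).

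In VAT, camera called 12 lists between the genotypes, 2 higher and 10 lower in KO. The lower ones were the macrophage, ribosomal, cell cycle and germinal center lists and those of oxidative phosphorylation (median -0.23), mitochondrially encoded (-0.28), adipocyte (-1.17), stromal (-0.65), endothelial (-0.98) and unfolded protein response genes (-0.17). Higher were B cell receptor signalling genes (0.19, 15 of 18 positive) and T cell markers (0.70). No list was called with an estimated correlation (lowest adjusted p = 0.6247), and fry called 0. Adjusted over the list alone, 2 macrophage markers (Lyz2 and Ccr2), 1 germinal center gene (Nuggc) and 1 adipocyte marker (Cfd) fell and 1 toll-like receptor gene (Tlr1) rose. In cohort 1 alone the median of the endothelial markers was 0.52, and with the replicate block 0.61, opposite to that of both cohorts. The list members named for VAT were chosen after their values were seen.

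The genes with the lowest p in VAT, all of which failed the correction at adjusted p = 0.672, were Ubxn10, listed at 0 in the 4 KO libraries and at 32.7 ± 12.1 (SD, n = 3) in WT, Pcdhga9 (-4.72, SE 0.77) and Robo1 (4.38, SE 0.75). Limma called 0 of 18676 genes, and 1373 had an unadjusted p under 0.05, where chance gives 934. The other members of the inflammasome list did not pass either, with Il1b, the cytokine that caspase-1 processes, at -0.91 (SE 0.47) and Panx1, a membrane channel, at -0.37 (SE 0.18).

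In the spleen, where the same question is asked of 4 KO and 4 WT libraries, no gene passed over all genes. Wdfy1 (ENSMUSG00000073643.11; chromosome 1, 79702262 to 79776143, minus strand) had the lowest p. It averaged 1880 ± 403 (SD, n = 4) in KO and 509 ± 55.0 (SD, n = 4) in WT, a log2 fold change of 1.84 (SE 0.21, adjusted p = 0.127). All 4 KO libraries lay above all 4 WT libraries, in a gene picked here for the lowest p of 16146. Mitochondrially encoded genes, which specify subunits of the respiratory chain, had positive fold changes for all 13 members (median 0.90). Among them mt-Nd1 averaged 33779 ± 6947 in KO and 17736 ± 2233 in WT (SD, n = 4 each; 0.98, SE 0.18), and the ribosomal RNA mt-Rnr1 stood at 0.78 (SE 0.15). The share of mitochondrially encoded transcripts was 2.07% ± 0.534 in KO and 1.09% ± 0.116 in WT libraries.

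Heat shock genes had lower values in KO spleen for all 13 members (median -0.57), with Hspa8 at -0.66 (SE 0.19) and Dnaja1 at -0.74 (SE 0.18). Germinal center genes had negative fold changes for 12 of 13 members (median -0.58), with Bcl6 at -0.72 (SE 0.18) and Aicda at -0.86 (SE 0.22). B-1 cell genes were positive for 17 of 21 members (median 0.41), with Zbtb32 at 1.08 (SE 0.30). Camera called 10 lists in the spleen, 3 higher and 7 lower in KO; after quantile normalization it also called 10, but 6 higher and 4 lower. Besides these 4 they were the sex-linked genes (0.88) on the higher side and cell cycle (-0.25), unfolded protein response (-0.42), follicular and naive B cell (-0.22), B cell receptor signalling (-0.22) and oxidative phosphorylation genes (-0.15) on the lower. With an estimated correlation camera called none of the lists (lowest adjusted p = 0.304), and fry called 0. Adjusted over the list alone, 12 mitochondrially encoded genes, 2 B-1 cell genes (Tcf4 and Zbtb32) and 1 sex-linked gene (Xist) rose, and 3 heat shock, 2 germinal center and 1 age-associated B cell gene (Rgs2) fell. Of the genes named for the spleen, those besides Wdfy1, mt-Nd1 and mt-Rnr1 were chosen after their values were seen.

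Limma called 0 of 16146 genes in the spleen, with 1145 at an unadjusted p under 0.05 against 807 by chance. Without KO replicate 1 it called 9 genes, all higher in KO: Wdfy1, mt-Cytb, mt-Co2, mt-Nd5, mt-Nd1, mt-Nd4, mt-Atp6, mt-Nd2 and mt-Nd6. Without KO replicate 4 it called Gm10052 as lower, a gene model chosen after its values were seen, and with sample quality weights or with no cohort term it called Wdfy1 alone. With the replicate block 17 lists were called in place of 10.

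Wdfy1 was also higher in KO in VAT, at 824, 1615, 924 and 705 against 652, 432 and 438 in WT (log2 fold change 0.92, SE 0.28, adjusted p = 0.672; exact 2-sided permutation p = 0.0571, where 0.0286 is the smallest possible). The mitochondrially encoded genes had the opposite sign in VAT, where all 13 were lower in KO. In tests chosen after the values were seen, the difference of the list's genotype effect between the tissues was -1.12 on the log2 scale (exact permutation of genotype within tissue, p = 0.000816, adjusted p = 0.0310 over 38 lists). With genotype permuted within cohort as well, the exact permutation p was 0.00167, the smallest that 600 arrangements can give, and no list passed (adjusted p = 0.0633). No other list passed in either permutation. Per gene, 0 of 15559 genes passed for a genotype effect that differs between VAT and spleen, with 1143 at an unadjusted p under 0.05 and 778 by chance.

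**Figure D1:**
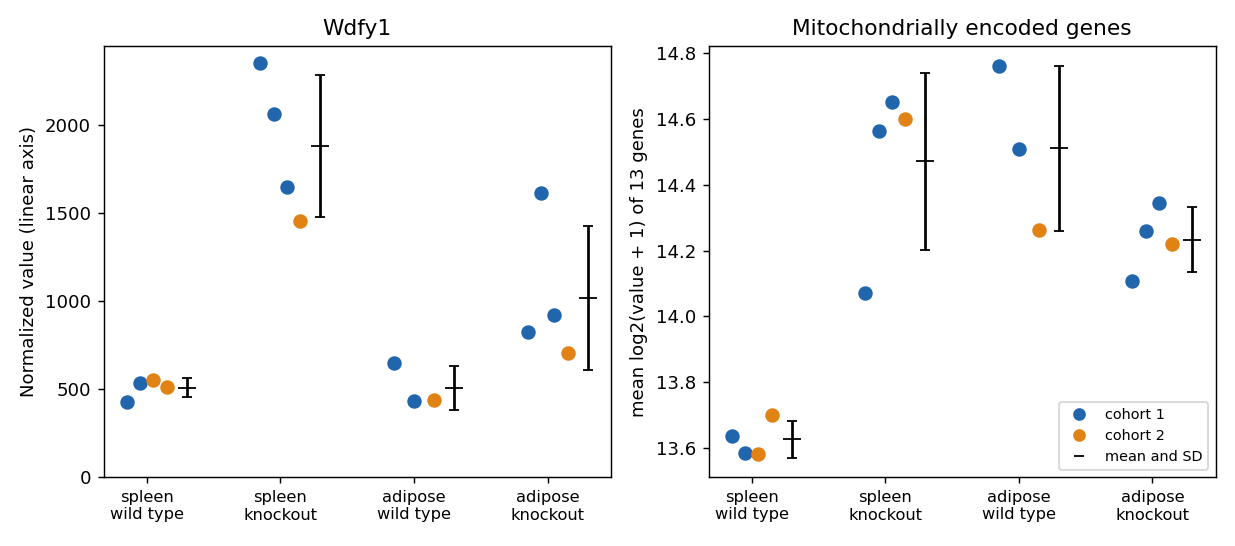
Wdfy1 (left, normalized value on a linear axis) and the 13 mitochondrially encoded genes (right, mean of log2(value + 1)) in each library of cohorts 1 and 2, with points for libraries colored by cohort and bars for the mean and SD of each group. Wdfy1 lies between 1458 and 2351 in the 4 KO spleen libraries and between 431 and 555 in the 4 WT ones; the mitochondrially encoded genes lie higher in KO than in WT in the spleen and not in VAT.

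Between tissues, WT B cells from VAT and from spleen differed in 3210 of 13744 genes, 2015 higher and 1195 lower in VAT (5 VAT and 4 spleen libraries). Immediate early genes, which cells induce within minutes of a stimulus, rose in VAT for 19 of 20 members (median 2.69): the transcription factor Fos (ENSMUSG00000021250.13; chromosome 12, 85473890 to 85477273) rose by 8.01 (SE 0.26, adjusted p = 3.16e-08). It averaged 43296 ± 32936 in VAT and 159 ± 63.8 in spleen. The orphan nuclear receptor Nr4a1 rose by 7.06 (SE 0.31), the phosphatase Dusp1 by 6.56 (SE 0.22) and Junb by 3.42 (SE 0.17). Heat shock genes rose for 9 of 13 members (median 1.42). The chaperones Hspa1b (9.95, SE 0.40) and Hspa1a (11.95, SE 1.02) are near-identical copies whose reads cannot be fully told apart. They averaged 99222 ± 13836 and 79119.9 ± 13463 in VAT against 119 and 45.2 in spleen. Dnajb1 rose by 2.75 (SE 0.17) and Hspb1 by 8.56 (SE 0.65).

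Genes of other adipose cell types rose in VAT in the same comparison. All 16 stromal and adipose progenitor markers rose (median 9.15): Dcn, the proteoglycan decorin (ENSMUSG00000019929.16; chromosome 10, 97479609 to 97518143), averaged 60448 ± 73547 in VAT and 1.17 ± 0.884 in spleen (14.22, SE 0.50), and Col3a1 rose by 11.96 (SE 0.73). Of the others, 10 of 11 endothelial markers rose (median 6.36; Cldn5 was listed at 0 in spleen), 10 of 15 macrophage markers (3.30; C1qb by 3.51, Trem2 by 6.39) and 5 of 9 adipocyte markers (4.01; Fabp4 by 10.27). The 8 largest rises past the threshold were Dcn, Col3a1, Hspa1a, Serping1, Retnla, Efemp1, Cyr61 and Igfbp6, of which Efemp1 and Cyr61 were listed at 0 in spleen. Fatty acid handling genes rose for 10 of 24 members and fell for 1 (median 0.81), with Lpl at 5.50 (SE 0.45) and Cd36 at 3.42 (SE 0.43).

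Genes that mark B cell subsets differed between the tissues as well. Follicular and naive B cell genes rose for 9 of 17 members and fell for 1 (median 0.53): Ccr7, a homing receptor, rose by 2.03 (SE 0.19; 31927 ± 7444 in VAT, 7629 ± 912 in spleen), Satb1 by 2.65 (SE 0.37) and Cd55 by 1.32 (SE 0.23). Of the 9 genes of the sort gate, 3 rose and 1 fell. Fcer2a, which encodes CD23, rose by 2.53 (SE 0.27; 14316 ± 3812 in VAT, 2537 ± 809 in spleen), Cr2, which encodes CD21, by 1.00 (SE 0.33, adjusted p = 0.0493) and Cd93 by 2.93 (SE 0.48), although the sort selected against these proteins. Endothelial and macrophage markers rose in the same comparison, and which cells gave the Cd93 transcripts was not tested. Cd3g fell by 1.69 (SE 0.49). Cd19 (-0.37, SE 0.22) and Ptprc (-0.29, SE 0.16) did not pass.

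Cell cycle genes fell in VAT for 21 of 23 members (median -1.67), with the replication factor Mcm6 at -1.22 (SE 0.18) and the spindle gene Tpx2 at -2.46 (SE 0.44). Plasma cell genes fell for 11 of 15 (median -1.34), with Txndc5 at -1.36 (SE 0.17), Mzb1 at -1.70 (SE 0.33) and Derl3 at -2.74 (SE 0.58). B cell receptor signalling genes fell for 12 of 18 (median -0.66), among them the receptor chain Cd79b (-1.35, SE 0.18), Cd72 (-1.38, SE 0.21) and the kinase Syk (-0.88, SE 0.14). Germinal center genes fell for 7 of 14 and rose for 1 (median -1.18): Rgs13 had -3.44 (SE 0.57), Mef2b -2.83 (SE 0.49) and Gcnt2, a glycosyltransferase, 7.21 (SE 1.19). Among the 8 largest falls, Apol7c and Btnl4 were listed at 0 in VAT, and the others were Izumo1r (-5.82), Tnfsf4 (-5.70), Gfi1b (-5.28), Stil (382 ± 116 in spleen, 27.4 ± 37.3 in VAT), Csn3 (-4.99) and Gramd2 (-4.87).

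Age-associated B cell genes split between the tissues, with 4 higher and 7 lower in VAT of 16 members, and camera did not call the list (adjusted p = 0.205). Fcrl5 fell by 2.12 (SE 0.18; 1187 ± 350 in VAT, 5020.1 ± 2065 in spleen) and the transcription factor Tbx21 by 2.04 (SE 0.29), while Nr4a2 rose by 7.65 (SE 1.19) and Rgs2 by 1.13 (SE 0.19). In the inflammasome and IL-1 family list 3 of 20 members rose and 2 fell. Il1b rose by 6.03 (SE 0.38, 1293 ± 331.4 in VAT, 19.0 ± 8.84 in spleen), Txnip by 1.91 (SE 0.15) and Nlrp3 by 3.79. The adaptor Pycard fell by 1.32 (SE 0.21) and Casp1 by 0.64 (SE 0.18). Nlrp3 was near the floor in spleen (0, 3.84, 0 and 11.8). Macrophage markers rose in the same comparison (10 of 15), and which cells gave the transcripts of this list was not tested. Mitochondrially encoded genes rose for 12 of 13 (median 1.08, mt-Nd2 by 1.24), and nuclear oxidative phosphorylation genes fell for 6 of 25 and rose for none (median -0.34, Cox5b by 0.65).

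**Figure D2:**
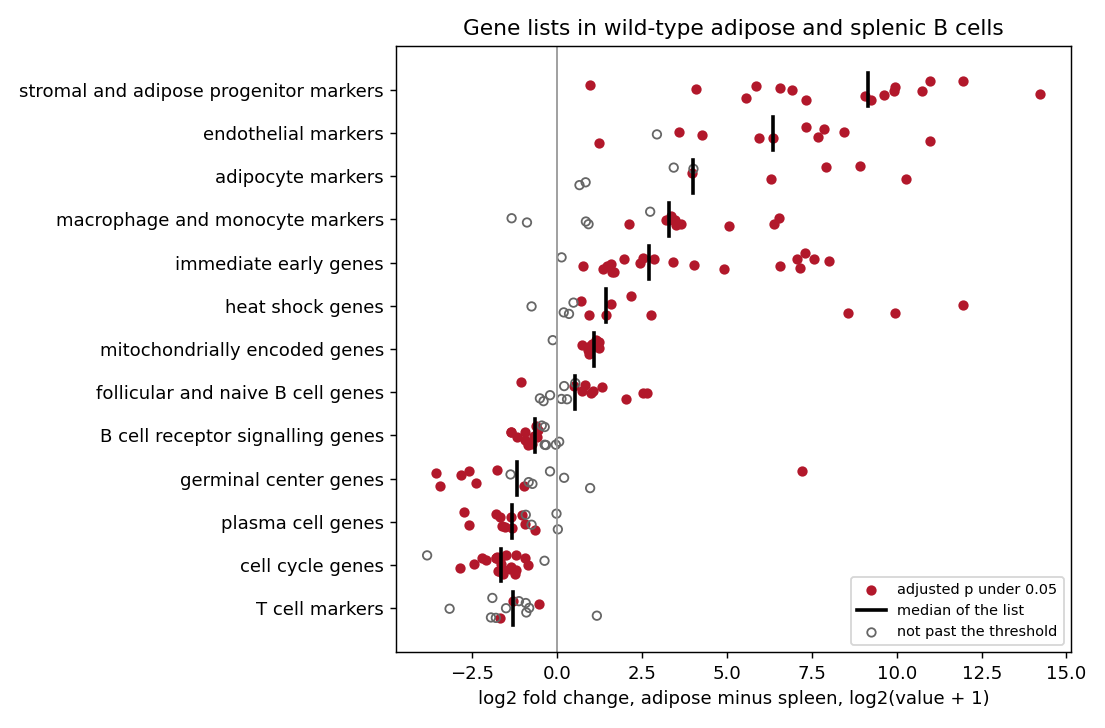
Log2 fold change, VAT minus spleen, of the members of 13 gene lists in WT B cells (horizontal axis, log2(value + 1) scale; 5 VAT and 4 spleen libraries). Each point is a gene, red where its adjusted p is under 0.05, and bars are list medians, from 9.15 for the stromal markers to -1.67 for the cell cycle genes.

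Camera called 17 of the 37 lists tested in the tissue comparison. The 9 higher in VAT were the stromal, endothelial, adipocyte, macrophage, immediate early, heat shock, mitochondrially encoded, fatty acid and follicular lists, and the 8 lower were the cell cycle, plasma cell, B cell receptor, germinal center, toll-like receptor (1 rose and 6 fell of 14), oxidative phosphorylation, unfolded protein response (2 rose and 6 fell of 16) and T cell lists (3 of 13 fell). With an estimated correlation none was called (lowest adjusted p = 0.134), while fry called 19, among them 15 of the 17. Adjusted over the list alone, 19 immediate early, 10 heat shock, 16 stromal, 11 endothelial, 12 macrophage, 7 adipocyte and 10 follicular genes rose, and 23 cell cycle, 11 plasma cell and 14 B cell receptor genes fell. The share of genes called that were higher in VAT, 62.8%, was 49.8% after quantile normalization, which moved the median fold change of all genes by -0.22. In cohort 1 alone 1300 genes were called, 907 higher and 393 lower.

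The age comparison in WT VAT sets 1 old library against 3 young ones in cohort 3, with the spread shared by all groups. Y-linked Eif2s3y stood at 607 in the old library and at 6.86, 2.22 and 1.86 in the young ones. Age and sex, as read from this gene, cannot be told apart in this comparison. The summed values of Ddx3y, Eif2s3y, Kdm5d and Uty were 2138 in the old library and 341, 1219 and 213 in the young ones. The sex of the young libraries is therefore not settled by these genes. Only Sass6 passed (ENSMUSG00000027959.13; chromosome 3, 116594982 to 116631004, plus strand), a centriole assembly gene, at 85.5 in the old library and 60756 ± 12814 (SD, n = 3) in the young ones (-9.44, SE 0.58, adjusted p = 0.0214). An antisense gene model, Gm42893, overlaps it and 1 of its retained-intron transcripts holds repeat sequence, so which transcript the values count is uncertain. Adjusted over the list alone, all 13 mitochondrially encoded, 13 of 16 stromal, 8 of 11 adipocyte and 6 of 20 immediate early genes fell, and 4 of 16 age-associated B cell genes (Cxcr3, Itgax, Fcrl5 and Cd80) and 2 of 14 germinal center genes (Nuggc and Mef2b) rose, members chosen after their values were seen.

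Camera called 12 lists for age in WT VAT, 4 higher and 8 lower in the old library (7 and 7 after quantile normalization). Lower were the mitochondrially encoded (median -2.61), stromal (-6.77), adipocyte (-6.26), endothelial (-3.09), erythroid (-4.06), immediate early (-1.23), heat shock (-0.53) and fatty acid lists (-0.55). Higher were the cell cycle (2.80), plasma cell (1.79), B cell receptor (0.78) and MHC class II lists (0.64). The median fold change of all genes in this comparison was 0.39. None was called with an estimated correlation (lowest adjusted p = 0.540), and fry called 0. Limma called 1 of 14422 genes, with 2231 at an unadjusted p under 0.05. Sass6 was not called without any 1 of the young libraries, after rescaling to the same total, with sample quality weights or with the replicate block, all of which called 0 genes. In all, 481 genes were called with no filter, 26 at a minimum value of 50 and 801 when only these groups were in the fit.

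The genotype comparison in old VAT, 3 KO libraries against 1 WT library, called no gene. MHC class II presentation genes had negative fold changes for all 10 members (median -0.45), with their regulator Ciita at 2059 ± 929 (SD, n = 3) in KO and 4222 in WT, and 31 of 34 ribosomal protein genes had positive ones (median 0.17), with Rpl30 at 1.12 (SE 0.24). Camera called these 2 lists, and neither with an estimated correlation (adjusted p = 0.977) nor with fry; adjusted over the list alone no member of either passed, and Ciita and Rpl30 were chosen after their values were seen. The genes with the lowest p, H1fnt, AF366264 and Tcp10a, were listed at 0 in all 3 KO libraries and at 86.6, 54.2 and 43.7 in the WT library (adjusted p = 0.188). Limma called 0 of 14422 genes, with 267 at an unadjusted p under 0.05 and 721 by chance; without KO replicate 3 it called 268, 266 of them lower in KO, and with no filter 197, all lower. Over 11574 genes in both tables, the genotype fold changes of cohort 3 and of VAT in cohorts 1 and 2 had a Pearson correlation of 0.04, a Spearman correlation of 0.05 and the same sign for 52.9%. Genes are not independent replicates.

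Because 1 old WT library stands alone, all 4 old libraries, 1 WT and 3 KO, were also compared with the 3 young ones, a comparison in which age and genotype are joined. Old libraries differed from young in 1872 of 12090 genes, 884 higher and 988 lower. Age-associated B cell genes rose for 4 of 16 members and fell for none, while 8 had positive and 8 negative fold changes (median 0.51), and camera did not call the list (adjusted p = 0.419). Fcrl5 (ENSMUSG00000048031.15; chromosome 3, 87435773 to 87500678), an Fc receptor-like protein, averaged 766 ± 366 in old and 26.9 ± 27.7 in young (5.11, SE 0.78). Itgax, the integrin CD11c, averaged 375 ± 310 and 1.93 ± 1.69 (6.71, SE 1.13), Cxcr3 rose by 6.57 (SE 0.98) and Cd80 by 6.50 (SE 1.13). Plasma cell genes rose for 4 of 15 members (median 1.46; 10 adjusted over the list alone), with the regulator Prdm1 at 6.51 (SE 1.21) and Mzb1 at 2.03 (SE 0.52), and Tnfrsf17 listed at 0 in young. Cell cycle genes rose for 4 of 23 (median 2.39; 9 adjusted over the list alone), with Mcm6 at 1.92 (SE 0.40), Bub1 at 5.24 (SE 1.00) and Cdc20 listed at 0 in young.

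Germinal center genes rose in old libraries for 3 of 14 members, with Aicda at 5.92 (SE 1.11) and Nuggc and Mef2b listed at 0 in young. B-1 cell genes rose for 4 of 21, among them Plscr1 (2.64, SE 0.56) and Zbtb32 (4.44, SE 1.14). Memory B cell genes rose for 2 of 12 and fell for 1, with Nt5e, which encodes CD73, at 5.37 (SE 0.85) and Zbtb20 at -2.28 (SE 0.31). B cell receptor genes rose for 2 of 18 (median 0.63; Dok3 by 1.40, Cd79b by 0.60). Follicular and naive genes fell for 4 of 17 and rose for 1: Fcer2a fell by 2.19 (SE 0.52; 2495 ± 1418 in old, 10621 ± 5302 in young), Klf2 by 1.55 (SE 0.35) and Ebf1 by 1.01 (SE 0.26), and Tnfrsf13c, the BAFF receptor, rose by 1.77 (SE 0.36). Cytokine genes rose for 1 of 20 and fell for 3. Il6 averaged 82.8 ± 35.9 in old and 4684 ± 2635 in young (-5.68, SE 0.58), and Il23a fell by 4.34 (SE 0.39).

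Every mitochondrially encoded gene fell in old libraries (13 of 13, median -2.60), with mt-Nd3 at -3.17 (SE 0.41) and mt-Co3 at -2.90 (SE 0.41), and these genes made up 11.1% to 31.8% of the values in young and 3.60% to 4.99% in old libraries. Immediate early genes fell for 10 of 20 (median -1.24), with Fos at -3.88 (SE 0.46) and Atf3 at -4.03 (SE 0.47). Heat shock genes fell for 3 of 13, with Hspa1b, uncertain as above, at -4.54 (SE 1.01), and the list's median of -0.32 became 0.15 after rescaling to the same total. Markers of 4 other cell types fell: 13 of 14 stromal (median -6.91; Sparc by 6.83, SE 0.53), 8 of 9 adipocyte (-6.53; Fabp4 by 5.78, SE 0.46), 6 of 9 endothelial (-3.66) and 5 of 6 erythroid and platelet markers (-4.02). Among the last, the globin copies Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, share most of their sequence. Fatty acid handling genes fell for 5 of 23 (median -0.74; Lipe -5.96, Lpl -6.32).

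The 8 largest rises in old libraries were Lipc, Pbk, Hist1h2ap, Ada, Zbtb48, Ap1m2, Chek1 and Gnb3, of which Pbk, Ada, Zbtb48, Ap1m2 and Chek1 were listed at 0 in all young libraries. Lipc, a lipase, rose by 7.60 (SE 1.10; 471 ± 531 in old, 1.09 ± 1.89 in young). The 8 largest falls were Sass6 (-9.25, SE 0.35, adjusted p = 1.51e-05; 104 ± 39.9 in old), Lum (-9.16, SE 1.35), Mfap4, Ebf2, Tmem182, Efna5, Heph and Mmp3, of which Lum encodes a matrix proteoglycan and Mmp3 a matrix protease. Cd19 (0.10) and Ptprc (0.27) did not pass.

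**Figure D3:**
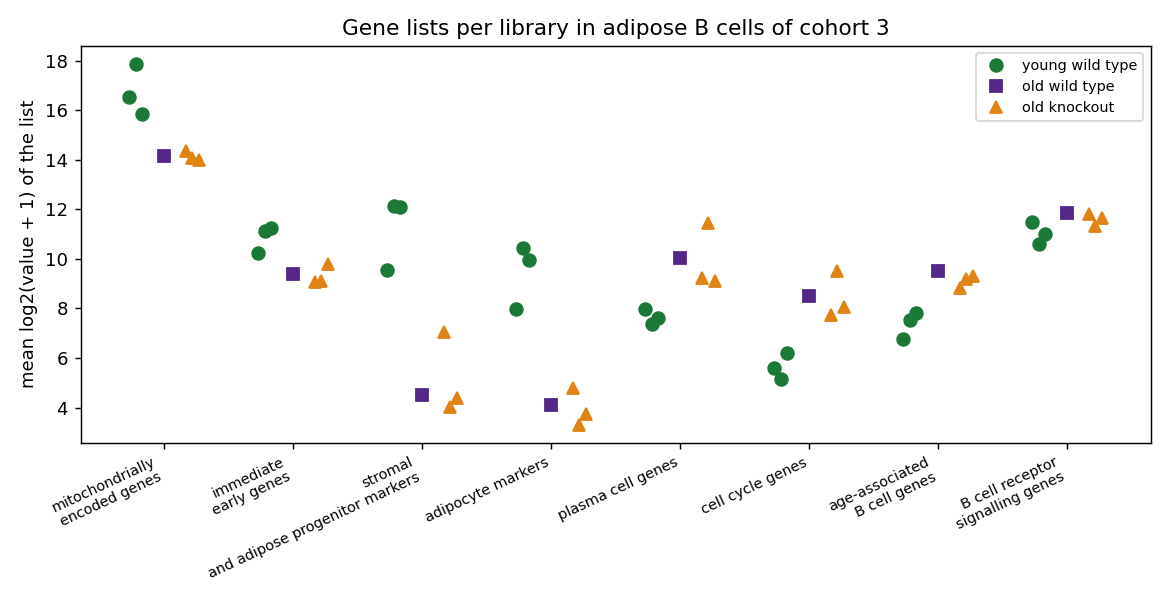
Mean log2(value + 1) of the members of 8 gene lists (vertical axis) in each VAT library of cohort 3, with a symbol per library for 3 young WT, 1 old WT and 3 old KO libraries. The mitochondrially encoded, immediate early, stromal and adipocyte lists lie higher in the young libraries, and the plasma cell, cell cycle and age-associated lists lie higher in the old ones.

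Camera called 11 lists between old and young, 3 higher (cell cycle, plasma cell and B cell receptor genes) and 8 lower (mitochondrially encoded, stromal, adipocyte, endothelial, erythroid, immediate early, heat shock and fatty acid genes). After quantile normalization it called 6 higher and 7 lower, and after rescaling to the same total 5 and 7. With an estimated correlation none was called (lowest adjusted p = 0.471), while fry called 10, among them 8 of the 11 and the age-associated list (adjusted p = 0.0219). The young libraries held 11846 to 12492 genes above 0 and the old ones 14078 to 15222. Of the genes called, 47.2% were higher in old libraries, and 64.5% after rescaling to the same total. The median fold change of all genes was 0.36, and that rescaling moved it by 0.47, to 0.83. Small positive list medians, such as those of the age-associated and B cell receptor genes, are to be read against this value. With sample quality weights 843 genes were called, with a sex term 1, without the old WT library 1156 and without young replicate 1 2887.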

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

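The tests of a genotype effect that differs between tissues were chosen only after the values were seen; the searches for samples far from their group were planned. Of 58 sets of 4 to 10 libraries searched, 4 held a library far from the others, where chance gives 2.9.

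The genotype effect on the mitochondrially encoded genes differed between the tissues by -1.12 on the log2 scale (VAT -0.28, spleen 0.84; exact permutation of genotype within tissue, 2450 arrangements, p = 0.000816, adjusted p = 0.0310 over 38 lists). With genotype permuted within cohort as well, the exact permutation p was 0.00167, the smallest that 600 arrangements can give, and the list did not pass (adjusted p = 0.0633). In the spleen the mean of the 13 genes was 13.58 to 13.70 in WT libraries and 14.07 to 14.65 in KO libraries, and in VAT 14.26 to 14.76 in WT and 14.11 to 14.35 in KO. Without KO replicate 1 of the spleen, whose level was 14.07, the difference was -1.26 (exact permutation p = 0.00163). No technical or biological explanation of this difference was tested.

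That same library, KO replicate 1 of the spleen, held 1.28% of mitochondrially encoded transcripts, far below the 2.29% to 2.43% of the other KO spleen libraries. WT replicate 4 of the spleen had 14.03% of its values in its top 10 genes, against 10.1% to 10.4% in the others. The adipocyte gene Adipoq was 1.99 in KO replicate 2 of the spleen and 0 in the other KO spleen libraries. Dcn, the stromal marker, was 187299 in WT replicate 4 of VAT and 9073 to 59154 in the other WT VAT libraries.

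For the difference between VAT and spleen in WT, a random grouping of the libraries can be excluded: of 100 splits drawn from 125, only the real 1 gave as many genes, 3210, and the highest other gave 1381. For genotype in VAT chance cannot be excluded: the real split gave 1373 genes at an unadjusted p under 0.05 and the highest other 1584, and 3 of the 35 splits gave as many. For genotype in the spleen it cannot be excluded either, with 1145 genes for the real split, 2240 for the highest other and 7 of 35 splits as large. That highest split puts all libraries of cohort 2, with KO replicate 1, against the rest, so with the cohort term it compares KO replicate 1 with the other 4 libraries of cohort 1. Cohort 1 alone and the replicate block each called 0 genes at an adjusted p under 0.05. For old against young libraries the real split gave 1872 genes and the highest other 0, so 1 of 35 splits was as large. That is the smallest share that 35 splits can give. Because this comparison was chosen after the values were seen, the splits do not exclude chance.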

How the results depend on the processing

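A sex term and the comparison of old libraries of both genotypes against young were chosen only after the values were seen.

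Gene counts: for genotype in VAT every alternative called 0, leaving out each library included. For genotype in the spleen sample quality weights called 1 and no cohort term called 1, leaving out each library gave 0 to 9 (9 without KO replicate 1), and the replicate block called 0. For tissue in WT cohort 1 alone gave 1300, leaving out each library gave 2185 to 3422, and the replicate block 2653. For age in WT VAT no filter gave 481, a minimum value of 50 gave 26, only the groups compared gave 801, and rescaling to the same total, sample quality weights and the replicate block gave 0, as did leaving out each young library (0 to 0). For genotype in old VAT no filter gave 197, and leaving out each KO library gave 0 to 268 (268 without KO replicate 3). For old against young sample quality weights gave 843, the sex term 1, the replicate block 1556, and leaving out each library 1156 (without old WT replicate 2) to 2887 (without young replicate 1). The cause of these changes was not tested, apart from the filters, which change which genes are tested.

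Gene lists: camera with an estimated correlation called 0 in all 6 comparisons. Fry called 0 for genotype in VAT, genotype in spleen, age in WT VAT and genotype in old VAT. For genotype in spleen the replicate block called 17 and cohort 1 alone 16, and for genotype in old VAT quantile normalization called 4 and the replicate block 8. The endothelial list for genotype in VAT reversed, from a median of -0.98 to 0.605 with the replicate block and 0.520 in cohort 1 alone.

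Of the 2454 alternative values for the 130 genes named for tissue, 2275 kept their direction and side of the threshold and 179 kept the direction only. For the 101 named for old against young these were 1329 and 274 of 1603. Leaving out the lone old WT library gives no estimate for age in WT and genotype in old VAT, so it was not run. The tissue comparison in KO, the joint fit of tissue and genotype, and the cohort 3 comparisons that need spleen were not run. Depth is unknown, so its limit on low genes such as Nlrp3 could not be computed.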

Other observations

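The slopes on the stromal markers, those of single members included, the tests of a fixed property of adipose B cells, the Wdfy1 tests of cohort and Nnt, and the whole comparison of old libraries of both genotypes against young, with its sex term, were chosen only after the results were seen.

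Cytokine genes rose in VAT over spleen in WT for 4 of 19 members and fell for 1, with Il6 at 6.82 (SE 0.74; 750 ± 276 in VAT, 9.004 ± 6.02 in spleen), the B cell attractant Cxcl13 at 5.98 (SE 1.15) and Ltb at -1.50 (SE 0.18). Adhesion and migration genes rose for 6 of 20 and fell for 4, with the chemokine receptor Cxcr4 at 1.56 (SE 0.21), Sell, which encodes L-selectin, at 0.72 (SE 0.15) and the integrin Itgal at -0.92 (SE 0.14). NF-kB targets rose for 4 of 17 and fell for 2 (Ier3 6.50, Tnfaip3 1.42), senescence genes rose for 4 of 10 and fell for 1 (Cdkn1a 3.69, Lmnb1 -0.93), and interferon-stimulated genes rose for 3 of 23 and fell for 1 (Oasl2 1.58, Mx1 -2.94). Marginal zone genes went both ways, 4 up and 4 down of 15 (Notch2 0.78, S1pr3 -2.02), as did B-1 genes, 2 and 2 of 21 (Myo1d 2.80, Spn -1.45), memory genes, 1 and 2 of 12 (Ccr6 0.99, Cd38 -0.74), NK cell markers, 1 and 3 of 13 (Rora 2.77, Ncr1 -3.69), and erythroid and platelet markers, 2 and 2 of 12 (Pf4 4.97, Slc4a1 -4.58). One gene each rose among glycolysis (Slc2a3 1.88), cholesterol synthesis (Insig1 0.73), MHC class II (H2-DMb1 0.75) and neutrophil genes (Csf3r 3.29), 1 fell among dendritic cell markers (Irf8 -1.09), and none of 34 ribosomal protein genes passed. Camera called none of these lists, and fry called the senescence and memory lists (adjusted p = 0.0456 and 0.0318).

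In old against young libraries interferon-stimulated genes rose for 2 of 22 and fell for 1 (Cmpk2 4.35, Ifit1 -3.28), cholesterol synthesis genes for 2 of 17 with 1 lower (Mvd 4.68, Ldlr -3.01), and dendritic cell markers rose for 1 of 10 and fell for 3 (Siglech -4.29; Itgae was listed at 0 in young). NF-kB targets rose for 1 of 17 and fell for 2 (Cd83 0.82, Icam1 -1.81), adhesion genes rose for 2 of 19 and fell for 2 (Itgb7 2.15, Ccr9 -2.60), and oxidative phosphorylation genes rose for 3 of 25 (Uqcrfs1 4.08, Cyc1 2.24). Macrophage markers fell for 1 of 12 (Lyz2 -2.42), sort gate genes for 2 of 9 (Fcer2a -2.19, Cd93 -3.07) and inflammasome genes for 1 of 20 (Il1r1 -5.38).

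In WT, 9 of 13 heat shock and 19 of 20 immediate early genes were higher in adipose than in splenic B cells. Stromal cells as the source of the heat shock transcripts are argued against: over the VAT libraries, where the stromal list ranged over 4.18 on the log2 scale, the called heat shock members had a mean slope of -0.0287 on it (-0.196 to -0.00458 on leaving out each library) and no member of 9 a slope of 0.5 or more. The mean of the called immediate early members had 0.276 (0.227 to 0.283), but 5 of 19 had a slope of 0.5 or more. These were Atf3, Egr1, Klf4, Fos (0.570, 0.483 to 0.644) and Fosb, picked by their slope. The sort selects against stromal cells, but the stromal marker Dcn was at least 9073 in every WT VAT library. For these genes, and for Zfp36 (0.417, 0.396 to 0.516), stromal cells as a source stay open. For the other 13, from Dusp1 (0.431; 0.409 to 0.475) to Egr3 (-0.144; -0.255 to -0.0832), the slope stayed under 0.5 whichever library was left out, which argues against stromal cells as their only source. A fixed property of adipose B cells, the same in young and old mice, was not decided on. Relative to B cell reference genes, and across separately normalized tables, old VAT of cohort 3 lay above the spleen of cohorts 1 and 2. The difference was 0.285 for the heat shock members (-0.463 to 0.844) and 1.15 for the immediate early members (0.960 to 1.41). In VAT of cohorts 1 and 2 it was 2.69 and 3.29. The old libraries lay lower than such a property would give. They differ from cohorts 1 and 2 in cohort as well as age, and no spleen of cohort 3 stood in their table, so the cause cannot be told. Young VAT of cohort 3 lay above that spleen by 1.58 (0.468 to 2.40) and 2.96 (2.02 to 3.63). These are medians over the members, so for young libraries such a property stays open for the members as a set. For Hspa1a and Hspa1b, picked after their values were seen, young VAT of cohort 3 held 0 to 534 and 182 to 700. WT VAT of cohorts 1 and 2 held 58852 to 91242 and 77968 to 111664, in a separately normalized table. A response to the release of cells from the tissue, which the labels do not describe, stays open and untested. So do a difference between cohorts and a difference of tissue that varies with age or library.

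Wdfy1 was higher in KO libraries of both tissues in cohorts 1 and 2. A difference between cohorts is argued against, since within each cohort and tissue the lowest KO value was 1.26 to 3.07 times the highest WT value. A substrain difference in Nnt is argued against by the Nnt fold change in the spleen, -0.415 (-1.002 to 0.173), and 0.40 in VAT. Other differences between substrains stay open. Ide had lower values in KO in the spleen (-0.56, SE 0.25) and in VAT (-0.27, SE 0.14), and neither passed. Entpd4, examined beside it, had -0.27 (SE 0.21) in the spleen and -0.19 (SE 0.26) in VAT and did not pass either. The loss of Nlrp3 and a variant carried along with the KO line, on chromosome 1 or elsewhere, stay open, and these data cannot separate them.

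Old libraries differed from young ones in genes of B cell subsets, of adipose cells and of mitochondria at once. More adipose carry-over in the young libraries may account for part of the falls. The sort for live CD45-positive, B220-positive and CD19-positive cells selects against stromal cells and adipocytes, but stromal transcripts were present. Dcn stood at 23213 to 65359 in young libraries and at 180 to 3250 in old ones. Of the genes lower in old, 58.1% (499 of 859) were higher in VAT than in spleen, against 13.99% of all genes and 4.23% of those higher in old. The binomial interval of 54.7% to 61.4% treats genes as independent, which they are not. Loss of transcripts from young libraries of lower complexity, which held fewer genes above 0, stays open for the rises. Of the genes higher in old, 31.8% were above 0 in all young libraries (28.7% to 35.0%, a binomial interval that also treats genes as independent). This decides nothing, since genes higher in old are chosen for low values in young. Sex stays open because only 1 old library lacks Y-linked Eif2s3y (2.34, against 227 to 1106 in the other old libraries and 1.86 to 6.86 in young); with a sex term 1 of the 1872 genes was called, but none changed sign, so the lost calls do not speak for sex. Without that library 1405 genes were called, and in it 97.7% of them lay beyond all young libraries. This goes against sex as the whole difference, but rests on a single library and on sex as read from Eif2s3y. Age itself and genotype stay open, untested apart.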
